A study of Mus musculus with 9 samples.

How the data were processed

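RNA was measured in ICOS+ CD4 T cells sorted from MC38 tumours of C57BL/6J mice on day 12 after tumour cell injection. MC38 is a mouse colon adenocarcinoma line that grows in this strain. Per the labels' protocols, cells were sorted by flow cytometry into lysis buffer, RNA was extracted with a micro kit, and, because each mouse gave little RNA, libraries were made with a single-cell RNA amplification kit and read as 76-nt pairs on a HiSeq instrument. The 9 libraries came from individual mice, 3 treated with anti-CTLA-4, 3 with anti-PD-1 and 3 controls. The control treatment, antibody clones, doses and number of sorted cells are not given in the sources used here.

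The deposited table holds raw counts per gene symbol for each library, with no normalization by the authors. TopHat2, HTSeq, DESeq2 and the build GRCm38 are named per the submitters' processing notes; their versions, the annotation and the HTSeq settings are not given in the sources used here. The table also holds HTSeq summary entries, which name no gene and were left out of library sizes and tests. Genes took 32.9% to 40.7% of all counts in a library, alignments outside any feature 27.1% to 42.0%, alignments that were not unique 24.3% to 31.1%, and ambiguous ones 0.631% to 1.13%. Reads shared by near-identical copies were therefore left uncounted, and genes with such copies are read low. Strand was checked with GENCODE mouse release M21: of 314 genes lying at least 80% inside exons of a gene on the opposite strand, 106 had an abundant partner, and their median count density relative to the partner was 0. Counting without strand would set reads that overlap both genes aside as ambiguous and could also give values near 0. The check therefore cannot by itself decide whether the counts separate antisense partners. The deposited counts are labelled as first-strand, though the strand setting is not stated.

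Gene counts summed to 25530333 to 41508589 per library. A count of 3, the floor used for a gene at 0, equals 0.0723 to 0.118 CPM, where CPM is the count scaled to 1e+06 gene counts. The reads carry no molecular identifiers, so floors cover counting error only. CPM values of genes and marker sums are printed without further factors, as mean ± SD over n = 3 mice. Fitted log2 fold changes also use TMM factors, which were 0.407 in anti-CTLA-4 replicate 2, 0.830 in anti-PD-1 replicate 2 and 1.06 to 1.26 in the other libraries, so a fold and the ratio of 2 CPM means differ where those libraries enter. Standard errors of fitted changes were taken as the change over the square root of F and are approximate. List levels, list differences and the list tests use log2 CPM with TMM factors. Fitted folds are not printed for genes with a group near 0.

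The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3; robust fit, TMM factors, genes kept by filterByExpr with a minimum count of 10) over all 9 libraries with the group as the only term, Benjamini-Hochberg adjusted p, and a threshold of 0.05. It tested 7858 of 45808 genes in each comparison of 2 groups and in 1 test over the 3 groups. Gene lists, 31 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 24 lists with at least 3 tested members. Camera with an estimated correlation and fry were run beside it. Summed CPM of 12 lists of markers of other cell types was compared with exact two-sided permutation tests, which cannot go below 0.1 for 3 against 3.

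Named genes were chosen by a rule written before the data were examined. From genes past the threshold with at least 5 CPM on average and no overlap between the libraries of the 2 groups, it took up to 12 with the largest rise and 12 with the largest fall. Where fewer than 5 passed in a direction, it added up to 5 genes of that direction with the smallest p. It always took Cd4, Icos, Ctla4, Pdcd1, Foxp3, Tbx21 and Ifng, and up to 4 called members of each list. Receptor segments, predicted genes, Rik clones and pseudogenes were left to counts. The groups, tests, lists and most alternatives were also fixed before the data were examined. Genes named outside the rule were chosen after their values were seen and are described as list members or as such.

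Alternatives covered DESeq2 1.42.0, RLE factors, library totals only, no filter and stricter filters on low counts, limma voom with quality weights, fits of 2 groups only, the replicate number as a block, each replicate left out in turn, receptor segments with mitochondrial and ribosomal protein genes left out, and a threshold of 0.10. Those added after seeing the data were leaving out the 2 libraries with the fewest genes, keeping genes with a mean of at least 100 CPM, and taking 0.1% of the other libraries' summed counts off each count.

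The fits were tested on simulated data with the means, library sizes and dispersions of these libraries over 7858 genes. Of 100 genes given a 64-fold change, the test recovered 40 in the anti-CTLA-4 comparison with controls, 25 in the anti-PD-1 comparison and 34 between the treatments. Of 100 genes given a 4-fold change it recovered 0 in each. No unchanged gene was called. Unchanged genes were drawn around the same mean in all groups, with no library set apart as anti-CTLA-4 replicate 2 was. In the real counts, other splits of the anti-CTLA-4 and control libraries called up to 56 genes. The simulation therefore does not give the rate of false calls in the real counts. In the list test, 20 S phase genes raised 8-fold gave an adjusted p of 0.000527 with camera at the preset correlation, 0.158 with the estimated correlation and 0.378 with fry. Low counts were modelled with MASS 7.3.60.0.1. Positions were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.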

Results

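Gene counts were obtained for 9 libraries of tumour-infiltrating ICOS+ CD4 T cells, 1 per mouse, from control mice and mice given antibodies against the inhibitory receptors CTLA-4 or PD-1 (n = 3 each). ICOS is a costimulatory receptor that marks activated T cells. Library totals ranged from 25530333 to 41508589 gene counts. The series asks whether the 2 antibodies act through different cellular mechanisms, and each antibody was compared with the controls and with the other.

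Several regulatory T cell genes, among them Foxp3 and Il2ra, were abundant in all 3 groups, while other members of the list, such as Gpr83 at 2.74 ± 4.72 CPM and Il10 at 4.63 ± 7.95 CPM in controls, were low. In anti-CTLA-4 replicate 2, Tnfrsf9, Nrp1, Ccr8, Capg and Klrg1 were below 1 CPM. Foxp3, the lineage transcription factor of regulatory T cells (ENSMUSG00000039521, GRCm38 chromosome X, 7573644 to 7595245), stood at 2770 ± 436 CPM in controls, 2260 ± 1180 CPM with anti-CTLA-4 and 3310 ± 541 CPM with anti-PD-1 (SD, n = 3). Il2ra, the high-affinity interleukin receptor chain, stood at 8170 ± 1950, 4270 ± 1870 and 6170 ± 772 CPM in the same order. Icos (ENSMUSG00000026009, chromosome 1, 60977927 to 61000320) was read at 2250 ± 539, 1400 ± 785 and 2760 ± 188 CPM, and Cd4 (ENSMUSG00000023274, chromosome 6, 124864692 to 124888221) at 506 ± 158, 258 ± 212 and 715 ± 96.2 CPM. Ctla4 (ENSMUSG00000026011, chromosome 1, 60887000 to 60915832), the target of one antibody, stood at 988 ± 203, 674 ± 194 and 569 ± 96.0 CPM. Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), which encodes PD-1, stood at 45.4 ± 44.7, 87.4 ± 151 and 101 ± 71.0 CPM. Tbx21, the Th1 transcription factor (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331), was read at 49.3 ± 64, 0.875 ± 1.44 and 37.9 ± 53.1 CPM, and Ifng, its interferon gamma target (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), at 8.88 ± 11.7, 31.8 ± 50.6 and 26.6 ± 18.0 CPM. None of these 7 fixed genes and Il2ra passed the threshold in any comparison.

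**Figure D1:**
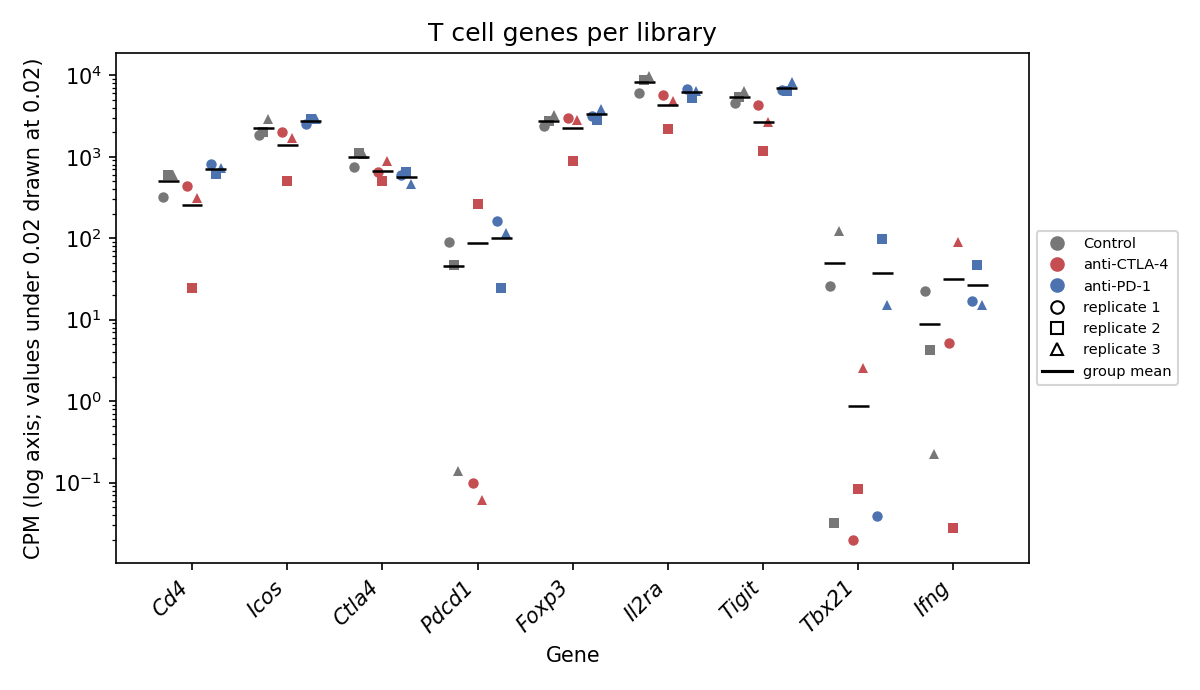
CPM on a log axis of 9 T cell genes in each library, coloured by group, with the replicate as the marker shape and a bar at the arithmetic group mean. Foxp3 lies between 2360 and 3900 CPM in 8 libraries and at 898 CPM in anti-CTLA-4 replicate 2.

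The libraries differed widely within groups. At least 5 CPM was reached by 6051 to 6309 genes in the control libraries, 5382, 2662 and 5124 genes in anti-CTLA-4 replicates 1, 2 and 3, and 5496, 4209 and 5878 genes in anti-PD-1 replicates 1, 2 and 3. Of the tested genes, 77.9% had fewer than 30 counts in one library and more than 1000 in another. The common dispersion corresponded to a coefficient of variation of 1.84 between mice. Anti-CTLA-4 replicate 2 stood apart: it held Cd4 at 24.5 CPM against 308 to 808 CPM elsewhere, and the myeloid genes Lyz2 at 1490 CPM, Tyrobp at 1870 CPM and Il1b at 1360 CPM, where the highest other values were 277, 146 and 103 CPM. Cd3e stood at 0.59 CPM in it against 347 to 838 CPM elsewhere, and Ptprc at 501 CPM against 2007 to 3733 CPM. Nos2 stood at 1287 CPM, where the highest other value was 146 CPM. Trac went the other way and was highest in it, at 632 CPM. Summed over 20 markers of macrophages and monocytes, anti-CTLA-4 replicate 2 reached 4865 CPM, against 930 to 3051 CPM in the other 8 libraries. Ccr2, which T cells also use, made up 800 CPM of that sum and 611 to 2127 CPM of the sums in the other 8. Fibroblast markers summed to 2154 CPM in anti-CTLA-4 replicate 2 and to at most 723 CPM elsewhere. Cd8a was at 0 counts in every library, and the CD8 marker sum was above 1 CPM only in anti-PD-1 replicate 3, at 125 CPM. Exact two-sided permutation tests of the marker sums cannot go below p = 0.1 with 3 against 3 and so decide little. Dendritic cell markers reached that value, without overlap, at 169 ± 71.6 CPM with anti-CTLA-4 against 54.2 ± 40.7 CPM in controls and 73.1 ± 29.2 CPM with anti-PD-1. So did B cell markers (0.00937 ± 0.0162 CPM with anti-CTLA-4 and 33.2 ± 31.9 CPM in controls), gamma delta T cell markers (0.193 ± 0.131 CPM with anti-PD-1 and 22.3 ± 37.4 CPM in controls) and the CD8 markers, near 0, with anti-CTLA-4 against controls. Each of these permutation tests had a Benjamini-Hochberg adjusted p of 0.655. The dendritic sum in anti-CTLA-4 replicate 3 was almost all Zbtb46, at 249.8 CPM. Cst3 went the other way, at most 0.0306 CPM with anti-CTLA-4 and at 69.8, 0.0643 and 27.8 CPM in controls. The B cell sum in Control replicate 1 was 0.0723 CPM, at the floor.

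**Figure D2:**
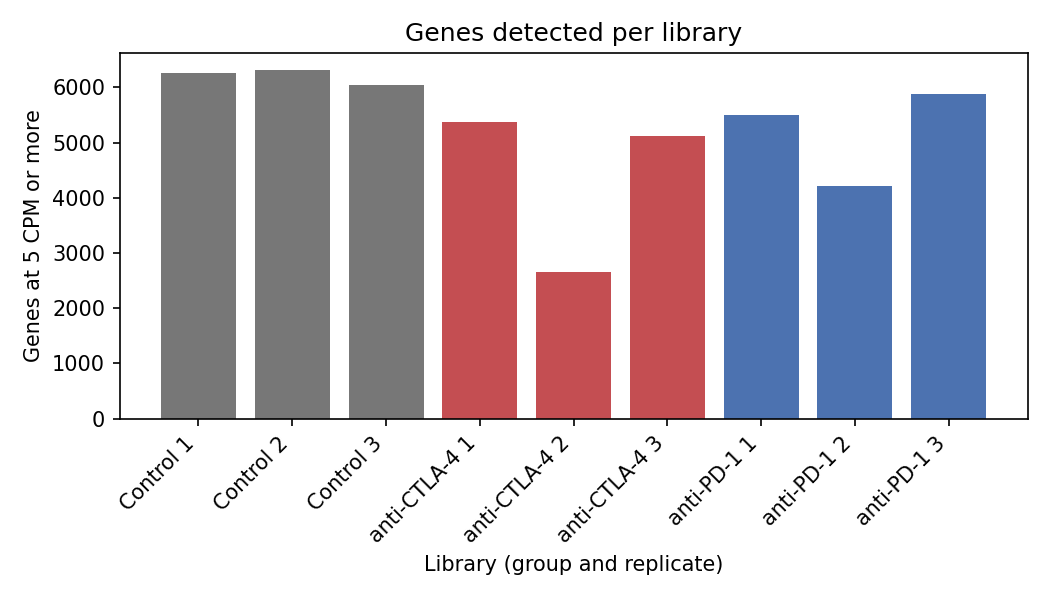
Number of genes at 5 CPM or more in each of the 9 libraries, coloured by group. Anti-CTLA-4 replicate 2 has 2662 genes and anti-PD-1 replicate 2 has 4209, below the other 7 libraries.

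With anti-CTLA-4, genes that were almost silent in controls were read at high levels mainly in 1 mouse. Fmn1, a formin that builds actin filaments, stood at 0.127 ± 0.0732 CPM in controls and at 73.0, 1010 and 52.9 CPM in the 3 anti-CTLA-4 libraries (adjusted p = 7.51e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Slc27a1, a fatty acid transporter, stood at 0.503 ± 0.634 CPM in controls and at 92.9, 925 and 7.99 CPM (adjusted p = 7.09e-05). Pfkfb2, a regulator of glycolysis, averaged 0.0481 ± 0.0212 CPM in controls and 228 ± 378 CPM with anti-CTLA-4, and Ldah, a lipid droplet hydrolase, 0.0895 ± 0.0285 and 239 ± 414 CPM. Mob1a, an activator of Hippo pathway kinases (ENSMUSG00000043131, chromosome 6, 83326016 to 83343776), was the only named gene past the threshold in this comparison with all libraries well above 0. It stood at 365 ± 187 CPM in controls and 1480 ± 1220 CPM with anti-CTLA-4, with 894, 2890 and 668 CPM in the 3 mice (log2 fold change 3.28, SE 0.68, adjusted p = 0.00146). Tulp3, Zfp948, St7l, Mapk11 and Tmem206 completed the named genes, with control means of 0.00803 to 0.0829 CPM and treated means of 92.5 to 195 CPM.

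**Figure D3:**
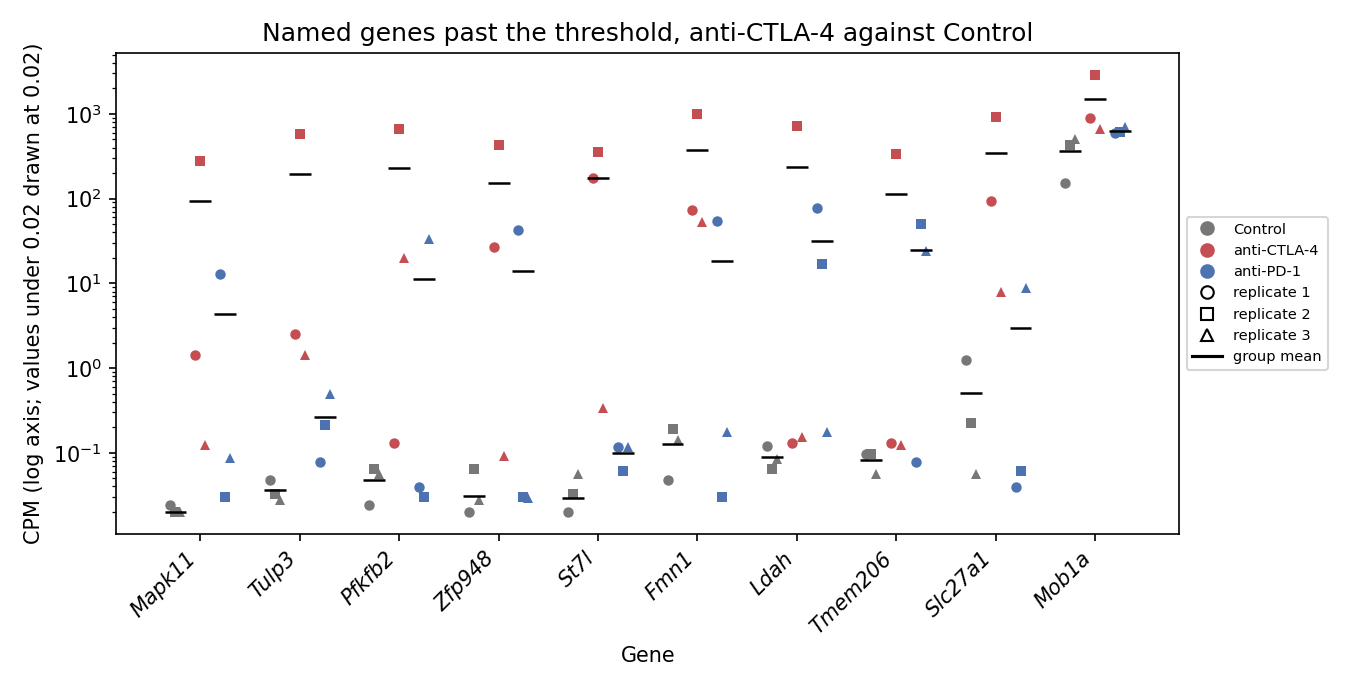
CPM on a log axis, by library, of the 10 named genes past the threshold for anti-CTLA-4 against controls, with the replicate as the marker shape and a bar at the arithmetic group mean. Anti-CTLA-4 replicate 2 is the highest library for each of the 10, and in Mob1a the controls span 154 to 509 CPM.

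In all, 29 genes passed the threshold for anti-CTLA-4 against controls, 29 higher and 0 lower with edgeR, of 889 with an unadjusted p under 0.05, while DESeq2 called 172 higher and 402 lower. For 28 of the 29 the highest library was anti-CTLA-4 replicate 2, and for 10 the groups did not overlap. Over all tested genes 11.9% had groups that did not overlap, where chance gives 10%. Without anti-CTLA-4 replicate 2 the edgeR test called 0 genes, of 410 with an unadjusted p under 0.05, and the count was 79 and 72 without replicates 1 and 3. It was 15 and 16 without Control replicates 2 and 3, and 52 without anti-PD-1 replicate 2. RLE factors gave 0 genes (1118 unadjusted), library totals only 0 (697), voom 0 (550), a fit of these 2 groups 1, a filter at 5 CPM in 3 libraries 18 and no filter 64. DESeq2 gave no adjusted p to any of the 29.

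The 5 lower genes with the smallest p were below 0.3 CPM in all anti-CTLA-4 libraries and did not pass. Ccl4, a chemokine made by activated T cells, stood at 120 ± 65.1 CPM in controls and 0.061 ± 0.0047 CPM with anti-CTLA-4 (adjusted p = 0.152), and the chemokine receptor Ccr1 at 146 ± 64.3 and 0.141 ± 0.0708 CPM (adjusted p = 0.163). Galnt6, a glycosyltransferase, stood at 118 ± 29.3 and 0.205 ± 0.0504 CPM, Zwint, a kinetochore protein, at 118 ± 97.9 and 0.0923 ± 0.0357 CPM, and the leukotriene receptor Cysltr2 at 126 ± 129 and 0.0524 ± 0.0399 CPM.

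No gene list passed camera for anti-CTLA-4 against controls, and no member of any list was called over all genes. The lowest adjusted p was 0.0754, for heat shock and dissociation stress genes, of which 12 of 15 had a positive fitted change, with Hspa8 at 900 ± 46.8 CPM in controls and 1150 ± 512 CPM treated. Adjusted over the list alone, 3 of 19 Th1 effector genes passed: Ccl4, and with higher fitted values Hopx (74.8 ± 40.9 and 378 ± 429 CPM) and Stat4 (28.9 ± 20.5 and 223 ± 387 CPM). Both were highest in anti-CTLA-4 replicate 2, at 846 and 670 CPM, and Stat4 was at 0.0656 and 0.275 CPM in replicates 1 and 3, below every control. Among 17 macrophage and monocyte markers, 2 passed over the list alone, Lyz2 and Ms4a7, both highest in anti-CTLA-4 replicate 2. Fry asks only whether a list moves one way, not whether it moves more than other genes. It gave an adjusted p of 0.0209 for lower Th1 effector, cholesterol synthesis and unfolded protein response genes. The mean TMM-scaled log2 CPM of each of these lists was lower in all 3 anti-CTLA-4 libraries than in every control (exact permutation p = 0.1, the lowest possible). Th1 effector genes stood at 5.53, 4.78 and 4.72 in Control replicates 1, 2 and 3, and at 3.342, 2.279 and 3.157 in the anti-CTLA-4 libraries. G2 and M phase and oxidative phosphorylation genes also reached that p. Most lists not made of cell type markers had a lower mean, as regulatory T cell (-1.3) and type I interferon response genes (-2.12). Th17 (2.21) and heat shock genes (0.834) went the other way. Detection was lower too, with 5382, 2662 and 5124 genes at 5 CPM in the anti-CTLA-4 libraries against 6051 to 6309 in controls. Fitted changes were mixed, with 10 of 19 Th1 effector, 5 of 14 cholesterol synthesis and 7 of 17 unfolded protein response genes positive. In the cholesterol list, Hmgcs1, an early enzyme of cholesterol synthesis, stood at 183 ± 65.3 CPM in controls and 0.0729 ± 0.0768 CPM with anti-CTLA-4, and Idi1 at 97.1 ± 65.9 and 0.0313 ± 0.0306 CPM. Camera, which compares a list with the other genes, gave the Th1 effector, cholesterol synthesis and unfolded protein response lists adjusted p of 0.542, 0.179 and 0.542.

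With anti-PD-1, the list of cytotoxic effector genes passed camera against controls at the preset correlation (adjusted p = 0.0438, the lowest of 24 lists) but not at an estimated correlation (0.74). Of 10 tested members 9 had a positive fitted change and none passed alone. The mean TMM-scaled log2 CPM of the members overlapped between the groups, at 4.6, 2.41 and 4.56 in Control replicates 1, 2 and 3 and at 4.48, 6.61 and 6.30 in the anti-PD-1 libraries (exact permutation p = 0.3). The granule protein gene Nkg7 (ENSMUSG00000004612, chromosome 7, 43437073 to 43438249) stood at 27.8 ± 32.4 CPM in controls and 319 ± 221 CPM with anti-PD-1, the protease gene Gzmb at 739 ± 423 and 1450 ± 369 CPM, the pore-forming protein gene Prf1 at 9.57 ± 16.4 and 118 ± 103 CPM, and the chemokine gene Ccl5 at 103 ± 55.8 and 218 ± 35.7 CPM. The median difference of the list was 1.53 on the same scale. The adjusted p was 0.489 with fry, 0.153 without Control replicate 2, 0.221 without anti-PD-1 replicate 2 and 0.0694 with RLE factors. The CD8 marker sum was 125 CPM in anti-PD-1 replicate 3 and below 0.2 CPM in replicates 1 and 2, where Nkg7 stood at 253 and 565 CPM.

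**Figure D4:**
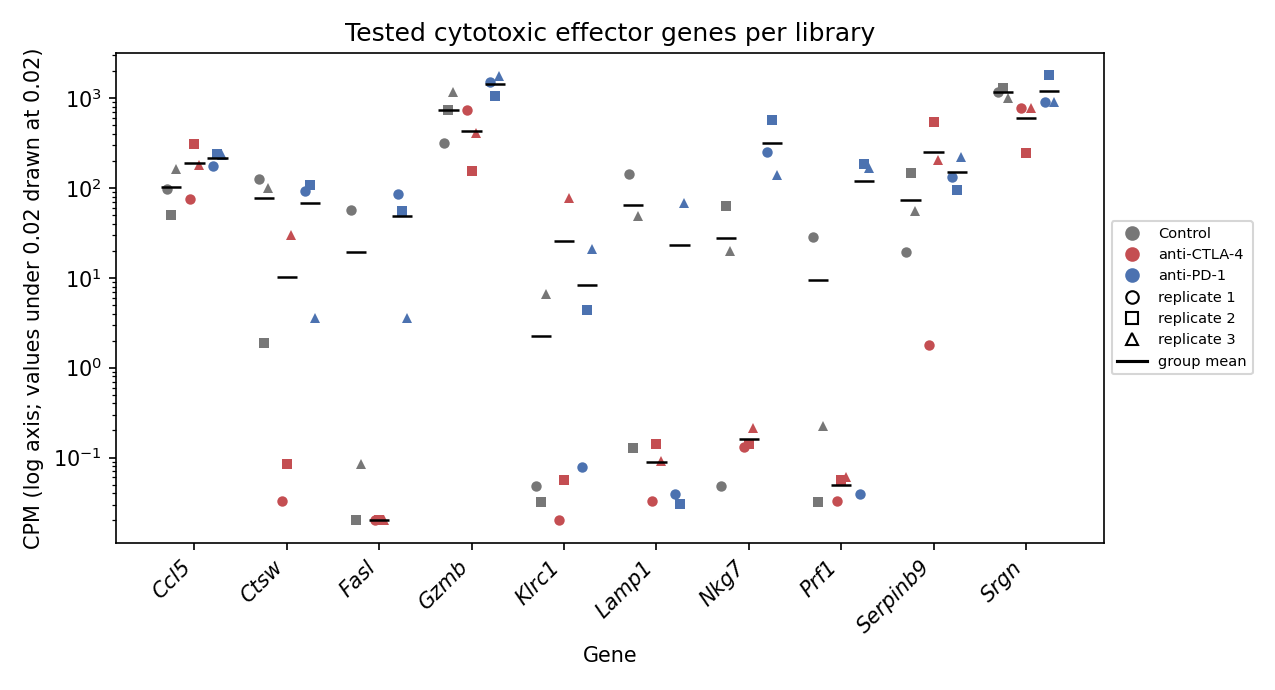
CPM on a log axis of the 10 tested cytotoxic effector genes in each library, coloured by group, with the replicate as the marker shape and a bar at the arithmetic group mean. Nkg7 lies between 138 and 565 CPM with anti-PD-1, at or below 63.5 CPM in controls and below 0.3 CPM with anti-CTLA-4.

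For anti-PD-1 against controls, 6 genes passed, 3 higher and 3 lower, of 472 with an unadjusted p under 0.05. Trim37, a ubiquitin ligase (ENSMUSG00000018548, chromosome 11, 87127077 to 87220683), stood at 90.8 ± 76.7 CPM in controls and 0.302 ± 0.107 CPM with anti-PD-1 (adjusted p = 0.00422). Abi3bp, a matrix protein gene, stood at 42.5 ± 19.0 and 0.278 ± 0.129 CPM (adjusted p = 0.0147), and Hn1l at 67.2 ± 27.4 and 0.238 ± 0.110 CPM (adjusted p = 0.0485). Rhot1, a mitochondrial transport GTPase, stood at 0.155 ± 0.118 CPM in controls and 90.0, 7.64 and 55.9 CPM in the 3 anti-PD-1 libraries, and Ldah at 0.0895 ± 0.0285 CPM and 77.6, 17.1 and 0.175 CPM (adjusted p = 0.0485 for both). Fmn1, whose groups overlapped, was the remaining higher gene. Higher genes that did not pass were Lrrc41 (0.0803 ± 0.0716 CPM in controls and 121 ± 110 CPM with anti-PD-1), Apex1, Unkl, Mapk11 and the mitotic kinase gene Pbk (0.0268 ± 0.0245 and 47.7 ± 82.5 CPM), with adjusted p of 0.108 to 0.823. Lower genes that did not pass were Rassf4 (18.8 ± 20.3 and 0.0296 ± 0.0292 CPM), Clcn6 (41.8 ± 37.9 and 0.0923 ± 0.0461 CPM), Pdxk, Atg4c and Pcdh19, with adjusted p of 0.0851 to 0.259. For 5 of the 6 the groups did not overlap, against 10.8% of all tested genes and 10% by chance. Each of the 6 had its highest value in anti-CTLA-4 replicate 2, a library that enters this comparison through the shared spread. None of the 6 passed without that library, without Control replicate 3, or without anti-PD-1 replicate 1. Left out singly, Control replicates 1 and 2 and anti-PD-1 replicate 3 left 1 of the 6 each, and anti-PD-1 replicate 2 left 3. DESeq2 called 421 genes, voom 2 (H2-K1 and Tigit), RLE factors 0 (511 unadjusted) and a fit of these 2 groups 0 (270 unadjusted). DESeq2 gave no adjusted p to any of the 6, and voom called none of them.

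Lists other than the cytotoxic one did not pass in this comparison, the next adjusted p being 0.377. Cholesterol synthesis genes were below every control in all 3 anti-PD-1 libraries (mean TMM-scaled log2 CPM 2 ± 0.721 against 3.79 ± 1.14). So were unfolded protein response genes (4.29 ± 0.0841 against 5.15 ± 0.189). Both reached the lowest possible exact permutation p of 0.1, as did Th2, S phase and fibroblast marker genes. Fitted changes were positive for 6 of 14 cholesterol synthesis and 10 of 17 unfolded protein response genes. The 25 regulatory T cell genes had 15 positive fitted changes, with Tigit at 5410 ± 913 CPM in controls and 7070 ± 1020 CPM with anti-PD-1, and Klrg1 at 843 ± 237 and 1390 ± 402 CPM. Of 20 S phase genes 7 had positive fitted changes, with Mcm4 at 40.4 ± 33.1 and 0.0429 ± 0.0159 CPM. The chemokine receptor gene Ccr2, fixed as a monocyte marker but also used by T cells, stood at 1050 ± 382 and 1880 ± 238 CPM without overlap (adjusted p = 0.949).

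Between the treatments, Nkg7 was lower with anti-CTLA-4 than with anti-PD-1. It stood at 0.131, 0.141 and 0.214 CPM with anti-CTLA-4 and at 253, 565 and 138 CPM with anti-PD-1 (adjusted p = 0.0236, edgeR's quasi-likelihood test), and without anti-CTLA-4 replicate 2 its adjusted p was 0.00101. It was the only gene called lower. The adjusted p ranged from 0.000125 to 0.56 over 21 alternative fits and was above 0.05 in 11, among them 0.16 with RLE factors, 0.0666 and 0.0571 without anti-CTLA-4 replicates 1 and 3, and 0.0801 and 0.359 without anti-PD-1 replicates 1 and 2. Prf1 stood at 0.0501 ± 0.0152 CPM with anti-CTLA-4 and 118 ± 103 CPM with anti-PD-1, Fasl at 0 counts in all 3 anti-CTLA-4 libraries and 48.6 ± 42.0 CPM, and Gzmb at 433 ± 295 and 1450 ± 369 CPM. Nkg7, Prf1 and Fasl passed when adjusted over the list alone, and the cytotoxic list as a whole had an adjusted p of 0.0525 (0.551 with an estimated correlation).

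Higher with anti-CTLA-4 were 64 genes. Plk1 and Kif20a, which drive mitosis, stood at 12.6, 404 and 0.0306 CPM and at 0.82, 380 and 0.0612 CPM with anti-CTLA-4, against 0.0396 ± 0.0343 and 0.0725 ± 0.0289 CPM with anti-PD-1 (adjusted p = 0.00652 and 0.0155). The macrophage gene Cd68 (105 ± 174 CPM against 0.0299 ± 0.0302 CPM) and the neutrophil gene Mmp9 (92.1 ± 152 against 0.0195 ± 0.0337 CPM) were called with adjusted p of 0.0271 and 0.032. Ebna1bp2, a ribosome assembly factor, was high in all 3 anti-CTLA-4 mice, at 119, 613 and 290 CPM, against 0.233 ± 0.077 CPM (adjusted p = 9.99e-05), and controls stood at 43.9 ± 45.8 CPM. Rassf4, Dock1, Zfhx4, Reep4, Atg4c, Pdxk, St7l, Hn1l, Polr1a and Tulp3 were the other genes with the largest rise, with anti-PD-1 means of 0.0296 to 0.262 CPM. The respiratory chain gene Atp5g1 was called as a list member at 218 ± 192 against 1.72 ± 2.74 CPM.

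In this comparison 65 genes passed, of 1106 with an unadjusted p under 0.05. For 64 the highest library was anti-CTLA-4 replicate 2, and for 23 the groups did not overlap, against 9.76% of all tested genes and 10% by chance. Without anti-CTLA-4 replicate 2, 6 genes passed, all lower with anti-CTLA-4, and 1 of the 65, Nkg7, remained. The 5 others were Ccr1, Galnt6, Pigc, Tigit and Zwint, named here after their values were seen. Leaving out anti-PD-1 replicates 1, 2 and 3 kept 27, 27 and 31 of the 65. The count was 145 and 131 without anti-CTLA-4 replicates 1 and 3. RLE factors gave 0 genes (1261 unadjusted), voom 0 (561), library totals only 6, a fit of these 2 groups 31, no filter 98 and DESeq2 852. DESeq2 gave an adjusted p to 2 of the 65 and called both. Lower genes that did not pass were Galnt6 (0.205 ± 0.0504 CPM against 250 ± 94.3 CPM), Zwint, Trnt1, which finishes transfer RNA ends (0.0728 ± 0.0388 against 199 ± 194 CPM), Ccl4 and Ccr1, with adjusted p of 0.0527 to 0.0865. No list passed camera, while fry gave lower Th1 effector genes an adjusted p of 0.0386, with 10 of 19 fitted changes positive. The mean TMM-scaled log2 CPM of that list was 3.342, 2.279 and 3.157 with anti-CTLA-4 and 5.265, 4.752 and 4.679 with anti-PD-1 (exact permutation p = 0.1, the lowest possible). Other lists also reached that p, among them cytotoxic effector and unfolded protein response genes. Of the 25 regulatory T cell genes 6 had positive fitted changes, and adjusted over the list alone Tigit (2700 ± 1560 against 7070 ± 1020 CPM) and Klrg1 (274 ± 276 against 1390 ± 402 CPM) passed. Heat shock and dissociation stress genes had 14 of 15 positive changes and an adjusted p of 0.0515 (0.551 with an estimated correlation).

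Over all 3 groups, 120 genes differed in the 3-group test, of 705 with an unadjusted p under 0.05. Without anti-CTLA-4 replicate 2 the count was 3, and it was 201 and 191 without replicates 1 and 3. RLE factors gave 19, library totals only 15, voom 6 and DESeq2 68.

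The 2 treatment comparisons shared 3 called genes, Fmn1, Ldah and Rhot1, each higher with both antibodies. Independent sets of 29 and 3 higher genes would share 0.0111, a value that ignores the shared controls. In 20 simulated sets of unchanged counts with shared controls 0 genes were shared, but these sets called 0 genes for anti-CTLA-4 and 0.05 on average for anti-PD-1, so they say little about the 3. Across genes, which are not independent replicates, the 2 effects correlated with r = 0.408 and a covariance of 3.41 on the log2 CPM scale. Unchanged groups simulated against shared controls gave r = 0.466 ± 0.246 and a covariance of 4.24 ± 2.33 (SD, 100 simulations). The controls, 3 libraries, are too few to split, and part of any excess may come from sharing them. No shared gene was left without anti-CTLA-4 replicate 2, without any one of the 3 controls or without anti-PD-1 replicate 1.

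T cell receptor segments were described apart. None was called in any comparison. The leading beta chain V segment differed between mice: Trbv13-2 in Control replicates 1 and 2, Trbv19 in Control replicate 3, Trbv3 in anti-CTLA-4 replicate 1 and anti-PD-1 replicate 1, Trbv17 in anti-CTLA-4 replicate 3 and Trbv20 in anti-PD-1 replicate 3. The beta chain V segments had 1 count in anti-CTLA-4 replicate 2 and 0 in anti-PD-1 replicate 2, where the floor was 0.0906 CPM. The alpha chain V segments had 3 counts in anti-CTLA-4 replicate 2, 5900 in anti-PD-1 replicate 2 and 2138 to 9833 in the other libraries.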

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

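The counts of called genes depended on the fit, on single libraries and on the scaling, and the cause was not tested except where named. The counts below are in the order anti-CTLA-4 against controls (29), anti-PD-1 against controls (6), anti-CTLA-4 against anti-PD-1 (65) and the 3 groups (120). They were 574, 421, 852 and 68 with DESeq2, 0, 0, 0 and 19 with RLE factors, 0, 0, 6 and 15 with library totals only, 64, 2, 98 and 160 with no low-count filter, 18, 3, 44 and 96 with at least 5 CPM in at least 3 libraries, and 0, 2, 0 and 6 with limma voom with quality weights. Fits of only the 2 groups compared gave 1, 0 and 31. Without receptor segments, mitochondrial and ribosomal protein genes they were 29, 3, 60 and 115, and at a threshold of 0.10 they were 50, 9, 105 and 148. DESeq2 split 172 higher and 402 lower, 130 and 291, and 359 and 493, where edgeR with TMM factors split 29 and 0, 3 and 3, and 64 and 1. RLE factors moved the median fitted change by 0.283, 0.193 and 0.123 and library totals by -0.225, -0.147 and -0.121. Leaving out 1 replicate gave 0 to 79, 0 to 5, 6 to 145 and 3 to 201 genes; the lowest values for anti-CTLA-4, the treatments and the 3 groups came without anti-CTLA-4 replicate 2. Chosen after seeing the data, leaving out the 2 libraries with the fewest genes gave 1, 2, 16 and 6, a mean of at least 100 CPM gave 0 each, and taking 0.1% of the other libraries off each count gave 3, 1, 8 and 7. None of the genes called without the 2 libraries was among the main calls, and the 1 for anti-CTLA-4, Galnt6, was lower. With 0.1% taken off, 1, 1, 4 and 5 were among the main calls.

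No pairing by replicate number was seen. Deviations of same-numbered libraries correlated at -0.0345 to 0.0182 and those of other-numbered libraries at -0.0229 to 0.0296. Of 9 libraries, 2 correlated best with their own number. No known pair was at hand to show that the check would detect pairing, so it cannot exclude it. With the replicate block the counts were 10, 1, 12 and 17.

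Lists past the threshold numbered 0, 1 and 0. For anti-CTLA-4 they were 1 with RLE factors and 3 with fry, and 0 to 3 with 1 replicate left out. For anti-PD-1 they were 0 with RLE factors, an estimated correlation, fry, and without the 2 libraries with the fewest genes, and 0 to 2 with 1 replicate left out. Between the treatments they were 1 with RLE factors, 1 with at least 5 CPM in at least 3 libraries and 1 with fry, and 0 to 5 with 1 replicate left out. The cytotoxic list for anti-PD-1 had an adjusted p of 0.0052 to 0.221 with 1 replicate left out, 0.0694 with RLE factors, 0.194 without the 2 libraries, 0.74 with an estimated correlation and 0.489 with fry. Shared called genes numbered 3, and 0 with RLE factors, 1 with at least 5 CPM in at least 3 libraries and 0 to 3 with 1 replicate left out. For genes named by the rule no called value changed sign among the fits that gave an adjusted p. Of their alternative values, 336 lost the threshold, 19 gained it and 40 that were never called changed sign. Outside the rule, Upp1, Arf4 and Ccnh, called higher for anti-CTLA-4 against controls, had negative fitted changes without anti-CTLA-4 replicate 2. Depth was not the limit: the spread between libraries hid 4-fold changes in simulated data.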

Other observations

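The counts of splits, the fits with 1 replicate left out and camera with an estimated correlation were planned. The other tests in this part were chosen after the result was seen, as was the use of the estimated correlation as a test of shared noise. With anti-CTLA-4, 22 genes were below 1 CPM in all 3 libraries and at 5 CPM or more in the other 6. They included Ccl4, Ccr1, Galnt6 and Zwint, the helicase Mov10 (56.9 ± 14.9 CPM in controls), the small GTPase Rhoc (70.7 ± 28.7 CPM), the signalling adaptor Traf3 (80.7 ± 77.5 CPM) and the transcription factor Myb (66.7 ± 52.6 CPM). The same count was 3 for the anti-PD-1 libraries and 0 for the controls. Dropout in anti-CTLA-4 replicate 2 was tested on the 28 sets of 3 libraries that include it. With the real set, 5 gave at least 22 genes, the highest other being 67, but the 4 others all held anti-PD-1 replicate 2, which also has few genes. Among the 21 sets without that library the real set was the highest, at 22 against 19, so dropout and an effect of the antibody both stay open.

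Splits of the libraries were counted for each number of called genes. For anti-CTLA-4 against controls the real split gave 29 genes and the highest other split 56, with 10 of 10 splits at 29 or more. For anti-PD-1 against controls the values were 6 and 8, with 2 of 10 splits at 6 or more, and between the treatments 65 and 68, with 3 of 10 splits at 65 or more. The 10 splits are too few for a share under 0.05. Among 100 of the 280 splits of all 9 libraries, 20 gave at least the 120 genes of the real groups and the highest other gave 143, so chance was not excluded for the 3-group count.

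More genes were called for anti-CTLA-4 than for anti-PD-1. The calls depended on the single library anti-CTLA-4 replicate 2: without it 0 of the 29 genes stayed called, while all 29 stayed without replicate 1 or replicate 3, and Mob1a went from a log2 fold change of 3.28 (SE 0.68) to 1.27 (SE 0.54). For 9 genes above all controls in that library neither other mouse was at 5 CPM or more and above all controls, though Tulp3 stood at 2.53 and 1.41 CPM there against at most 0.0482 CPM in controls, while for 16 genes 1 was, as St7l at 173 CPM and Oas1b at 139 CPM in replicate 1 and Rhot1 at 93.1 CPM in replicate 3, and for Fmn1, Slc27a1 and Mob1a both were. St7l and Fmn1 lost their call with a large change left and a wider error (SE 3.13 to 5.19 and 2.01 to 4.74), Arf4 and Ctsb with little change left, and mt-Rnr2 was above all controls in no library. If few molecules stood behind this library, each detected gene would take a larger share of its reads, and its genes at 5 CPM or more had a median 1.42 times the highest of the other libraries, between the bounds set, which leaves this open. In anti-CTLA-4 replicate 2, Cd3e stood at 0.59 CPM against 347 to 838 CPM elsewhere, while Trac was highest there, at 632 CPM. Alpha and beta chain V segments had 3 and 1 counts in that library. RNA of myeloid cells, which the sort for ICOS+ CD4 T cells would remove, and an effect of the antibody remain open and untested.

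The list of cytotoxic effector genes passed camera for anti-PD-1 against controls with 0 of 10 members called and overlapping list levels (exact permutation p = 0.3). Noise shared by the members within libraries stays open: the adjusted p was 0.74 with the estimated correlation, but a list raised 8-fold in simulated counts failed there too, at 0.158. RNA of CD8 T cells or natural killer cells, which the gate for CD4 would remove, stays open. In anti-PD-1 replicates 1 and 2, Cd8a, Cd8b1, Ncr1, Klrb1c, Klre1 and Eomes summed to 0.0144% of the Nkg7 CPM, but 5 of the 6 had 0 counts in all 9 libraries, Cd8a even where Cd8b1 stood at 125 CPM, so their zeros decide nothing. The natural killer list, mostly Klra4 and Tyrobp, held 40.8 and 147 CPM there against 21.4 to 128 CPM in controls, and an effect of anti-PD-1 remains open as well.

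Many genes had a few counts in a library where they were otherwise silent, and these low counts were larger for genes with many counts elsewhere. Genes at 100 counts or fewer in a library had a median of 0 counts where the other 8 libraries summed to 1000 to 10000, and of 3 counts where they summed to 10000 to 100000. If reads were assigned to the wrong library, the low counts would rise in proportion to that sum. The median slope on log scales was 0.56, between the bounds set for and against it, so it cannot be told apart from other sources. For a low true level of each gene, the dispersion around a constant share was 4.29 (median over the 9 libraries), above the bound that this explanation needed. Genes at 100 counts or fewer can mix low true levels with misassigned reads, so this dispersion cannot decide between the 2. In anti-CTLA-4 replicate 2, with the most such genes (7047), the slope was the highest, at 0.743, and the dispersion the lowest, at 2.43. Taking 0.1% of the other libraries off each count gave 3 genes for anti-CTLA-4 against controls in place of 29. Of these 3, 1 was higher and 2 were lower, and only 1 was among the 29. The TMM factor of anti-CTLA-4 replicate 2 was then 1.05 in place of 0.407, so the low counts also act on the scaling, and the 2 effects were not separated. The 0.1% exceeded the median ratio of the low counts to the other libraries' sum, which was 0.00776% to 0.0198% by library. The pooled ratio was 0.0355% in anti-CTLA-4 replicate 2 and up to 0.113% in the others. What misassigned reads at the median ratio would do was not tested.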
